A study of Rattus norvegicus with 6 samples.

How the data were processed

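Total RNA from the tibialis anterior of both legs of 3 rats was measured on 6 arrays, 1 per muscle. Samples were grouped by their titles, and those whose title marks them with the abbreviation Cont were taken as contralateral, a word the labels do not spell out. The number in each title gave the animal. Per the labels, the ipsilateral muscle was compared with the contralateral muscle of each animal. The reference point of the 8 weeks of survival is not stated there, and was read as following the nerve repair.

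The deposited values are intensities on a linear scale, 1 per probe set and array, with 9 values at 0. Their mean without the lowest and highest 2% was about 150 on every array, as found from the values. The software that made the deposited intensities is not given in the sources used here. Of 15923 probe sets, 57 were control probe sets and were left out. A platform annotation, which can be old, gave 1 gene symbol for 12789 probe sets, several for 312 and none for the 2822 it does not list. Gene IDs or accessions of 12756 probe sets were found in a gene table of assembly GRCr8, which changed 1 symbol. Names only were taken from it, and no positions are given. Probe sets with several symbols were not named.

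Values were used as log2(intensity + 15.8), the pseudocount being the 20th percentile of all values. Because the medians of the 6 arrays lay within 0.115 of each other on the log2 scale, under the limit of 0.2 set beforehand, the arrays were not normalized further. Probe sets with a mean log2 value above the 40th percentile of the non-control ones (5.86, an intensity of 42.4) were tested, which left 9519. The test was limma 3.58.1 in R 4.3.3 (lmFit, then eBayes with an intensity trend), with the animal as a fixed block and Benjamini-Hochberg adjustment over all tested probe sets. It had 2 residual and 7.47 prior degrees of freedom. The median standard error was 0.16. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.

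The pairing comes from the design, since both muscles are of 1 animal. Deviations from the group means correlated between the muscles of an animal at -0.04 for animal 4, 0.07 for animal 5 and 0.13 for animal 6, over probe sets. Log2 values of any pair of libraries correlated at 0.95 to 0.976 over probe sets.

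A total of 22 gene lists were fixed before the data were examined, as were the design, the alternatives and the rule for named genes. Lists were tested with camera (preset inter-gene correlation of 0.01) on the brightest probe set per gene, where at least 5 genes were tested, which held for 21. Camera with an estimated correlation and the rotation test fry were run beside it. The former rests on only 2 residual degrees of freedom, which by itself makes a list less likely to pass. Its estimate was also far above the preset 0.01 in several lists. It was 0.77 for slow-twitch, 0.54 for glycolysis, 0.50 for denervation and 0.43 for fast-twitch genes, but 0.049 for developmental muscle and -0.023 for extracellular matrix. Where the estimate is high, the preset counts genes that move together almost as independent, so camera's small p-values overstate the evidence. Of the 21 lists, 10 passed camera, 7 higher and 3 lower, 0 passed with an estimated correlation and 0 passed fry. For changes in either direction fry passed 1, the fibroblast and tendon list, at an adjusted p of 0.018. The named genes were the 12 with the largest positive and the 12 with the largest negative difference, up to 4 members of each list with the smallest p, and a fixed set of genes of denervation and fibre type, part of which is not reported here. Because none passed the adjusted threshold, the first part was filled with genes of unadjusted p under 0.05 and 1 direction in all 3 animals. By chance, 12.5% of genes have a given sign in all 3 animals.

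The procedure was tested on simulated data of 9519 probe sets for the ipsilateral against contralateral comparison. It called 38.8% of the probe sets changed 1.5-fold, 98.5% of those changed 2-fold and 100% of those changed 4-fold. There were 15 false calls among 9319 unchanged ones. Each simulated change had the same size in every animal, so these shares do not hold for changes that differ between animals. Myh3, which did differ so, had an adjusted p of 0.28 in limma's fit of the real data. Alternatives covered the block, the pseudocount, the normalization, the filter, the variance prior, the choice of probe set, the list test and each animal left out. A pair of alternatives that leave out libraries with spermatid transcripts was chosen after seeing the data.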

Results

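Gene expression was measured in the tibialis anterior muscle of 3 male Wistar rats, aged 8 weeks, in which a nerve to the muscle had been cut and later repaired. The peroneal nerve was transected and its end sutured to another muscle, the biceps femoris. After 4 weeks the proximal and distal stumps of the nerve were sutured together, and the animals survived for 8 weeks. RNA from the ipsilateral muscle and from the contralateral muscle of each animal was hybridised to 1 rat expression array per muscle, which gave 6 libraries, 3 per group. The animals carry the numbers 4, 5 and 6. Each array held 15923 probe sets, and its trimmed mean intensity was about 150. Median intensities ran from 60.3 to 66.6. The number of arrays limits the precision. Differences are given as log2 of ipsilateral over contralateral intensity, after a pseudocount of 15.8, with the standard error (SE) from limma over 3 pairs. This scale understates differences of dim genes. Group intensities are means ± SD of 3 libraries.

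The comparison asked how the formerly denervated muscle differed from the contralateral muscle of the same animal after nerve repair. As groups, transcripts of slow-twitch and developmental muscle proteins were higher in the ipsilateral muscle, and transcripts of fast-twitch proteins and of glycolysis and glycogen enzymes were lower, in a list test with a preset correlation between genes. None of these 4 list calls held with an estimated correlation (adjusted p = 0.549 to 0.632) or with the rotation test fry, and the glycolysis call was also lost without animal 5. For the slow-twitch genes the differences were large in animals 5 and 6 and small in animal 4. The largest difference among the named genes was that of Myh3, the embryonic myosin heavy chain, with an intensity of 63.9 ± 87.1 contralaterally and 528 ± 349 ipsilaterally. Its log2 difference was 3.19 (SE 0.56, n = 3 pairs), with 0.85 in animal 4, 4.65 in animal 5 and 4.06 in animal 6. No single gene passed the adjusted threshold, so all values of single genes below describe measured differences that did not reach it.

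In limma's paired fit over 9519 probe sets, which stood for 7117 named genes, 0 had a Benjamini-Hochberg adjusted p under 0.05, and the lowest adjusted p was 0.2. At an unadjusted p under 0.05 there were 605 probe sets, 340 higher and 265 lower, where chance alone gives 476. The result rested on animal 4. Without that animal 241 probe sets passed, 148 higher and 93 lower, whereas 0 passed without animal 5 and 0 without animal 6. The fit without animal 4 had only 1 residual degree of freedom, so its variances came largely from the prior. Of those 241, only 102 (42.3%) had the same sign in animal 4. Over all tested probe sets the within-animal differences of animals 5 and 6 correlated at 0.42, those of animals 4 and 5 at -0.01 and those of animals 4 and 6 at -0.17. These are correlations across genes, which are not independent replicates. Both arrays of animal 4 also had lower intensities of the cre hybridisation spike, 1117 contralaterally and 1476 ipsilaterally, against 2481 to 3605 on the other 4 arrays. The ratio of the 3' to the middle actin probe set was 2.77 in contralateral 4 and 2.87 in ipsilateral 6, against 1.36 to 1.68 in the others. A difference of at least 1.5-fold in the same direction in all 3 animals was found for 17 probe sets, 12 higher and 5 lower. The count was 8 with a pseudocount at the 40th percentile and 32 without the filter on dim probe sets. With fewer animals to agree, it was 249 without animal 4, 34 without animal 5 and 50 without animal 6. With the sign of animal 4 turned there were 21 such probe sets, with that of animal 5 turned 1, and with that of animal 6 turned 2.

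The slow-twitch fibre list rose as a group. Of its 15 tested genes, 8 were higher in all 3 animals and 0 were lower in all 3, and its median log2 difference was 0.94 (camera adjusted p = 1.46e-14; adjusted p = 0.56 with an estimated correlation). The list median was 0.08 in animal 4, 1.61 in animal 5 and 1.08 in animal 6. Adjusted over the list alone, 11 of the 15 genes passed, against 0 when adjusted over all genes. Myh7, the slow myosin heavy chain, had an intensity of 684 ± 232 contralaterally and 2377 ± 1132 ipsilaterally, a log2 difference of 1.71 (SE 0.36). Its other tested probe set gave 1.52. Myl2, a slow myosin light chain, was higher by 1.01 (SE 0.19), but its dimmer probe set gave 0.35 (SE 0.22), with -0.23 in animal 4. The slow troponins Tnnc1, Tnni1 and Tnnt1 were higher by 0.92 (SE 0.19), 1.25 (SE 0.31) and 1.32 (SE 0.33). The other tested probe set of Tnni1 gave 1.13 (SE 0.32), with -0.058 in animal 4. Csrp3, a Z-disc protein, went from 768 ± 316 to 2421 ± 890, a difference of 1.64 (SE 0.32).

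The fast-twitch fibre list fell as a group, with a median log2 difference of -0.25 over 18 genes (camera adjusted p = 1.46e-05; adjusted p = 0.563 with an estimated correlation). The list median was -0.19 in animal 4, -0.54 in animal 5 and -0.036 in animal 6. In 7 genes the ipsilateral value was lower in all 3 animals and in 1 it was higher in all 3. Adjusted over the list alone, 2 genes passed. Myh4, the fast type IIb myosin heavy chain, had an intensity of 2641 ± 191 contralaterally and 1476 ± 661 ipsilaterally, a difference of -0.92 (SE 0.19). Actn3, the fast-fibre alpha-actinin, differed by -0.48 (SE 0.13) and Mybpc2, the fast myosin-binding protein C, by -0.39 (SE 0.13). A dimmer probe set of Mybpc2 gave -0.79 (SE 0.38), with 0.52 in animal 4. Mss51, a muscle gene found mostly in fast fibres, had the largest negative difference among the named genes, -1.40 (SE 0.29).

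**Figure D1:**
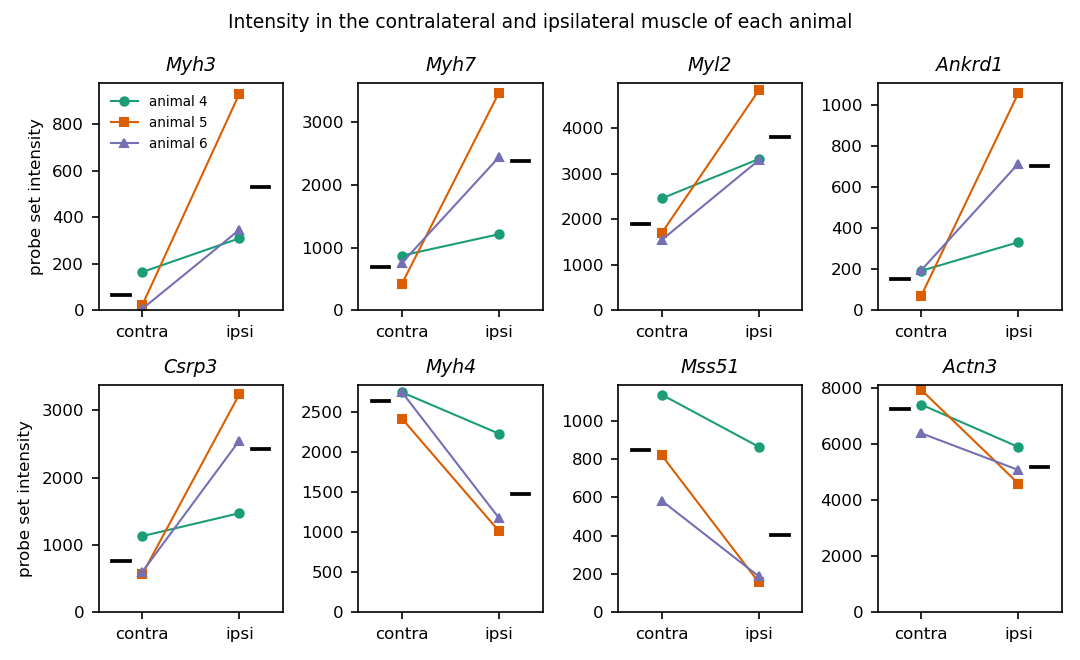
Probe set intensity on a linear axis from 0 for 8 genes in the contralateral (contra) and ipsilateral (ipsi) muscle, with 1 line per animal and a black bar at each group mean of 3 libraries. Myh3, Myh7, Myl2, Ankrd1 and Csrp3 were higher and Myh4, Mss51 and Actn3 lower in the ipsilateral muscle of each animal, and for Myh7 the difference was 0.47 in animal 4 against 2.99 in animal 5 and 1.67 in animal 6.

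Genes of developing and regenerating muscle rose as a group, with a median of 0.37 over 10 tested genes (camera adjusted p = 9.77e-06; adjusted p = 0.549 with an estimated correlation). Its median was 0.18 in animal 4, 0.50 in animal 5 and 0.18 in animal 6. In 6 of the 10 the value was higher in all 3 animals, and 2 passed when adjusted over the list alone. After Myh3, the largest named member was Myl4, the embryonic myosin light chain, higher by 0.94 (SE 0.20). Nes, the intermediate filament protein nestin, was higher by 0.44 (SE 0.16) and Dlk1 by 0.39 (SE 0.16). The denervation-responsive list also rose, with a median of 0.41 over 12 genes (camera adjusted p = 9.77e-06; adjusted p = 0.56 with an estimated correlation). Its median was -0.15 in animal 4, 0.90 in animal 5 and 0.59 in animal 6. The stretch-responsive Ankrd1 went from 153 ± 70.6 to 701 ± 363, a difference of 2.05 (SE 0.41), and Sln, the calcium pump regulator sarcolipin, was higher by 1.59 (SE 0.41). Runx1 and Ampd3 were higher by 0.46 (SE 0.19) and 0.67 (SE 0.30), each with a value below 0 in animal 4.

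The acetylcholine receptor and neuromuscular junction list did not pass (median 0.17 over 9 genes, camera adjusted p = 0.131). It passed in a setting chosen after seeing the data, without the pairing and ipsilateral 4 (adjusted p = 0.0193). In the paired fit of all libraries, its adjusted p was 0.563 in camera with an estimated correlation and 0.543 in fry. Chrna1, the receptor's alpha subunit, differed by 0.37 (SE 0.23), with -0.36 in animal 4, 0.90 in animal 5 and 0.57 in animal 6. Chrnb1 differed by 0.29 (SE 0.17) and Chrnd by 0.19 (SE 0.22). The fetal subunit Chrng and the adult subunit Chrne lay below the filter on dim probe sets and were not tested, with intensities of 9.73 ± 3.27 and 39.1 ± 19.3 contralaterally and 9.2 ± 0.96 and 50.0 ± 20.1 ipsilaterally. Ncam1, a neural adhesion molecule, was also below it, at 30.1 ± 17.9 and 36.4 ± 2.65. The muscle transcription factor Myog differed by 0.56 (SE 0.27), with -0.31 in animal 4, and Myod1 by 0.01 (SE 0.15).

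The glycolysis and glycogen list fell (median -0.22 over 23 genes, camera adjusted p = 0.00105; adjusted p = 0.632 with an estimated correlation). Its members Pfkm, Gpd1 and Pygm are also in the fast-twitch list, so the falls of these lists are not fully separate. Of the 23 genes, 8 were lower and 2 higher in all 3 animals. Without animal 5 its camera adjusted p was 0.482. Phka1, a subunit of phosphorylase kinase, differed by -0.72 (SE 0.20), the phosphofructokinase Pfkm by -0.43 (SE 0.16) and Pgm1 by -0.37 (SE 0.13). Their dimmer probe sets gave -0.43, -0.64 and -0.40, with values of 0.25, 0.32 and 0.31 in animal 4. The fatty acid uptake and oxidation list rose (median 0.16 over 29 genes, camera adjusted p = 0.0134; adjusted p = 0.563 with an estimated correlation). The list median was -0.084 in animal 4, 0.26 in animal 5 and 0.19 in animal 6. Its camera adjusted p was 0.0697 without the pairing by animal, 0.19 without animal 5 and 0.218 without animal 6. The fatty acid transporter Cd36 was higher by 0.57 (SE 0.17) and Lpl, lipoprotein lipase, by 0.45 (SE 0.19) with -0.14 in animal 4, while Pdk2, a kinase that inhibits pyruvate dehydrogenase, differed by -0.47 (SE 0.18). A dimmer probe set of Pdk2 gave -1.04 (SE 0.23). The oxidative phosphorylation and citric acid cycle list did not pass (median -0.01 over 54 genes, camera adjusted p = 0.816).

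**Figure D2:**
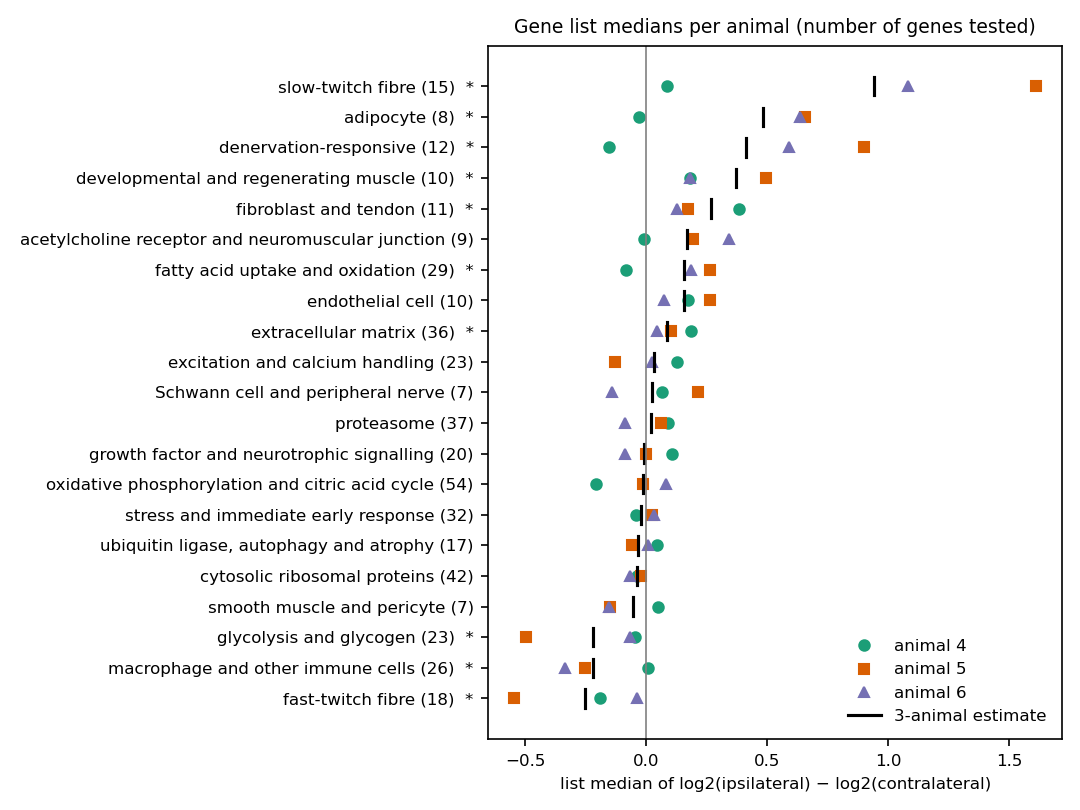
Median log2 difference, ipsilateral minus contralateral, of each tested gene list, with 1 symbol per animal, a black bar for the median of the 3-animal estimates, the number of tested genes in brackets, and an asterisk where camera's adjusted p was under 0.05. The slow-twitch fibre median was 0.08 in animal 4, 1.61 in animal 5 and 1.08 in animal 6.

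Extracellular matrix genes rose as a group, by a small median of 0.09 over 36 genes (camera adjusted p = 0.000717; adjusted p = 0.549 with an estimated correlation), and 14 of them were higher and 4 lower in all 3 animals. Per animal, its median was 0.18 in animal 4, 0.10 in animal 5 and 0.044 in animal 6. Adjusted over the list alone, 8 passed higher and 1 lower. Thbs4, a thrombospondin of muscle and tendon, went from 212 ± 52.2 to 517 ± 98.8, a difference of 1.23 (SE 0.22). Ccn2, connective tissue growth factor, was higher by 1.42 (SE 0.37), Postn, periostin, by 0.94 (SE 0.23) and Fmod, fibromodulin, by 0.83 (SE 0.20). Spp1, osteopontin, differed by -0.84 (SE 0.18). The fibroblast and tendon markers, 6 of which are also in the matrix list, rose by a median of 0.27 over 11 genes (camera adjusted p = 0.000454; adjusted p = 0.56 with an estimated correlation). Animal 4 had the highest list median, 0.38, against 0.17 in animal 5 and 0.13 in animal 6. The adjusted p was 0.0238 without animal 4, and the call was lost without the pairing and ipsilateral 4 (adjusted p = 0.0591), a setting chosen after seeing the data. The tendon gene Tnmd was higher by 0.68 (SE 0.15).

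Markers of other cells moved with these groups. Adipocyte markers rose by a median of 0.48 over 8 genes (camera adjusted p = 7.36e-05; adjusted p = 0.56 with an estimated correlation). The list median was -0.028 in animal 4, 0.66 in animal 5 and 0.64 in animal 6. Of the 8 genes, 4 were higher and 1 was lower in all 3 animals. Cfd, adipsin, was higher by 0.79 (SE 0.16), Fabp4 by 0.52 (SE 0.16) and Scd by 0.51 (SE 0.15). Markers of macrophages and other immune cells fell, with a median of -0.22 over 26 genes (camera adjusted p = 0.000635; adjusted p = 0.563 with an estimated correlation). The list median was 0.0088 in animal 4, -0.25 in animal 5 and -0.33 in animal 6, and without animal 6 the adjusted p was 0.192. Cd14 differed by -0.52 (SE 0.16), Cd74 by -0.40 (SE 0.16) and Cd68 by -0.38 (SE 0.16). Endothelial markers (median 0.16, camera adjusted p = 0.111), Schwann cell and nerve markers (0.02, adjusted p = 0.764) and smooth muscle and pericyte markers (-0.06, adjusted p = 0.364) did not pass, and only 4 erythroid genes were tested, too few for the list test. The endothelial list passed without the filter on dim probe sets (adjusted p = 0.0446). With the filter, its adjusted p was 0.56 in camera with an estimated correlation and 0.464 in fry.

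Lists of general cell functions did not pass. The camera adjusted p was 0.91 for ubiquitin ligases, autophagy and atrophy, 0.593 for excitation and calcium handling, 0.816 for growth factors, 0.764 for stress responses, 0.764 for ribosomal proteins and 0.764 for the proteasome. The atrophy-related ubiquitin ligase Trim63 differed by -0.22 (SE 0.15), and Fbxo32 was too dim to be tested, at 47.4 ± 8.00 contralaterally and 39.3 ± 22.9 ipsilaterally. Igf1 differed by -0.15 (SE 0.15), and its other probe set by 0.06. Of 20 named genes with more than 1 tested probe set, Igf1 was the 1 whose probe sets had opposite signs. Rcan1, a calcineurin regulator, was higher by 0.86 (SE 0.20).

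Among the other genes with large differences in 1 direction in all 3 animals, Sncg, gamma-synuclein, went from 153.0 ± 39.4 to 727 ± 398, a difference of 2.0 (SE 0.36). Bex1 was higher by 1.81 (SE 0.42), the matrix protein Mfap4 by 1.46 (SE 0.25) and Atp1b4 by 1.41 (SE 0.25). Lower values were found for Grm8, a glutamate receptor, by -1.26 (SE 0.25), Tnk2 by -0.97 (SE 0.25), Tmub2 by -0.95 (SE 0.16), the somatostatin receptor Sstr3 by -0.89 (SE 0.19), Pgap6 by -0.88 (SE 0.20), Enpp2 by -0.84 (SE 0.24), Chac1 by -0.82 (SE 0.22) and Tuba8 by -0.78 (SE 0.24). Cish differed by -0.89 (SE 0.25), on a contralateral intensity of 101 ± 99.7. Probe sets too dim to be tested gave 0.18 and -0.26 for Grm8 and 0.35 for Pgap6 in the fit without the filter.

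Prm1, a protamine that packs sperm DNA, was higher by 1.42 (SE 0.31). Prm1 had an intensity of 617 in the ipsilateral and 175 in the contralateral library of animal 4, of 72.4 and 56.7 in animal 5, and of 248 and 39.5 in animal 6. Tnp1, chosen after its values were seen, was at 216 and 60 in animal 4, 43.6 and 14.4 in animal 5, and 100.2 and 29.9 in animal 6. Of 22 testis genes not looked at before, 4 had their highest value in the ipsilateral library of animal 4, where chance gives 3.67. The ipsilateral library of animal 4 was the one with the most Prm1 and Tnp1, and came from the animal with the smallest median differences in the slow-twitch and denervation-responsive lists, though not in the fast-twitch, extracellular matrix or fibroblast lists.

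**Figure D3:**
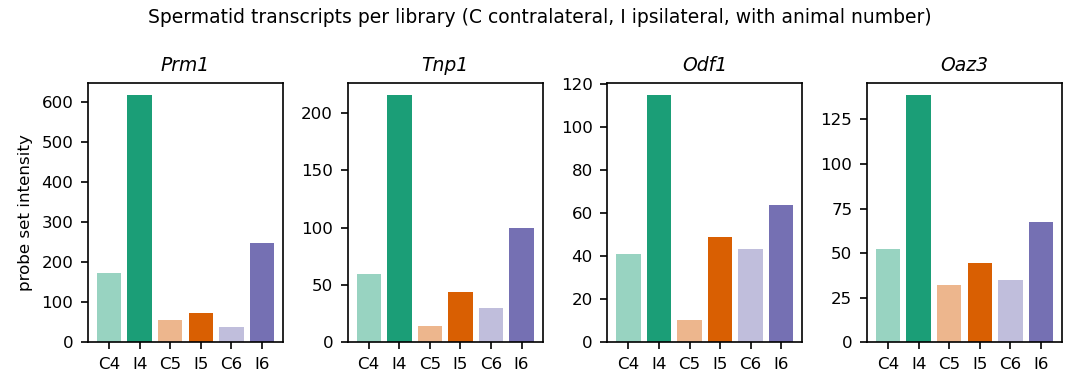
Probe set intensity, on linear axes from 0, of 4 spermatid genes in each of the 6 libraries, with 1 bar per library. The highest bar of each gene is the ipsilateral library of animal 4, where Prm1 was at 617 and Tnp1 at 216.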

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

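The 10 probe sets named first were picked out because they lay below the filter on dim probe sets, outside the comparison, while each ipsilateral library exceeded each contralateral one and the filter's intensity of 42.4. The tests of induction, of a flatter signal, of exchanged labels and of a lower share of fibre RNA were chosen only after the results were seen, and the others in this part were set beforehand. The test of adipose tissue replaced an earlier one on Fabp4, Scd and Cfd, whose values had been seen.

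The ratio of mean intensities, ipsilateral over contralateral, was 1.36 for Nr1i2, 1.41 for Batf3, 2.01 for Tex101, 1.97 for Col10a1, 1.74 for Ubl7, 1.66 for Abracl, 1.79 for Lrp8 and 1.5 for Pcsk5, and 1.2 and 1.5 for a pair of probe sets that have no name here. For Col10a1 the intensities were 26.4 ± 4.99 and 52.1 ± 5.51 (SD, n = 3). Of all 6347 dim probe sets, 240 were without overlap in this direction, fewer than the 317 (5%) that chance gives. None of the 57 control probe sets met these conditions.

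Spermatid transcripts were the first pattern: Prm1, Tnp1 and Odf1 were higher ipsilaterally, and 13 of 15 testis genes, chosen with their values in view, were highest in the ipsilateral library of animal 4. A candidate source is trace testis RNA in some libraries, and its test on 22 testis genes not looked at before came out at chance, with 4 of them highest in that library (18.2%, exact binomial interval 5.19% to 40.3% at 95% confidence, one-sided exact p = 0.512, 3.67 expected). Most of the 22 were dim, so the test leaves the source open. Induction by the injury and repair would place every ipsilateral library above every contralateral one, but over 9 spermatid genes the median gap between the lowest ipsilateral and the highest contralateral library was -0.18 on the log2 scale and 6 gaps were below 0. Because those genes were picked for the pattern and animals can differ in level, induction stays open too.

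Animal 4 was the second pattern: over 37 genes of the slow-twitch, developmental and denervation lists its median difference was 0.07, against 1.04 in animal 5 and 0.63 in animal 6, although in the developmental list alone animals 4 and 6 were alike (0.18 in both, 0.50 in animal 5). A flatter signal on its ipsilateral array is argued against by a slope of 0.98 of that library on the other ipsilateral ones over all tested probe sets. Its contralateral array was not tested in this way. Other faults of both arrays stay open, since both had a low hybridisation spike (1117 and 1476, against 2481 to 3605). The ratio of the 3' to the middle actin probe set does not set animal 4 apart. It was 2.77 in contralateral 4 and 1.36 in ipsilateral 4, but 2.87 in ipsilateral 6. Exchanged labels of its muscles would turn the 241 probe sets called without it to about -0.92, if its response were as large. That size is raised by their selection in animals 5 and 6. Their median in animal 4 was -0.059 (SE 0.028 over probe sets, which are not independent). Only 102 of the 241 had the same sign there, and turning animal 4 gave an unadjusted count of 1114 against 605. An exchange with a smaller response therefore stays open. Partial mixing of its RNA samples remains possible. Over the 37 genes its contralateral library lay at a median of 0.21 (SE 0.12 over genes) above the other contralateral ones. Its ipsilateral library lay at -0.67 (SE 0.11 over genes) from the other ipsilateral ones. These SEs treat genes that move together as independent, and do not measure how libraries vary. A smaller response of that animal, a biological difference, was not tested and stays open.

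Cell type markers were the third pattern, with adipocyte and fibroblast markers higher and immune markers lower, although in animal 4 the adipocyte median was -0.028 and the immune median 0.0088. A lower share of muscle fibre RNA would raise all other cell types alike. The fibroblast median exceeded the immune median in each animal, by 0.42 on average (SD 0.044 over the animals). For the adipocyte median the gap was -0.037 in animal 4 and 0.61 on average (SD 0.57). These lists were picked because they had moved apart in the same data. Their gap therefore cannot decide the question, and a lower share stays open. More adipose tissue in the ipsilateral sample may account for the adipocyte markers, and Fabp4, Scd and Cfd were higher in all 3 animals, but they belong to the list that showed the pattern. A test set beforehand on adipocyte genes outside the lists did not pass in limma's camera, with p = 0.322 at the preset correlation and p = 0.563 with an estimated correlation. Of its 9 genes 4 were higher in animals 5 and 6, with a median of 0.04 over all, so more adipose tissue stays open, as does a change in the muscle fibres, which was not tested.

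Other splits of the 6 libraries are too few, at 10, for a share under 0.05. The adjusted count was 0 in the real split and at most 0 in the others, as in all 10. The unadjusted count was 605, and the highest other was 1114, with 4 splits at least as large. These 4 are not all separate. Splits that part only 1 pair rest, with the animal as a block, on the difference of that animal alone. The count of 958 came from a couple of such splits, which are the same fit of animal 5. Lists past camera numbered 10 in the real split and 2 to 9 in the others, so that only the real split reached 10. Camera at the preset correlation thus passed lists in every split. Of the 4 splits that part all 3 pairs, 2 gave at least 17 probe sets of 1.5-fold in all animals, and the highest other was 21. The highest counts of 1114, 21 and 9 came from the split that turns animal 4, which points to a structure in which animal 4 stands apart from animals 5 and 6.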

How the results depend on the processing

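The settings that leave out ipsilateral libraries with spermatid transcripts were chosen after seeing the data, and the others beforehand. The adjusted count was 0 in each planned setting except without animal 4, so that leaving out 1 animal gave 0 to 241. It was 87 without the pairing and ipsilateral 4, and 57 without the pairing and ipsilateral 4 and 6. That last setting leaves 1 ipsilateral library, which is assumed to vary like the contralateral ones, the only source of the spread. Without the pairing but with all libraries it was 0, with 564 at an unadjusted p under 0.05. The block therefore moved no gene call, and of the list calls only fatty acid uptake and oxidation (adjusted p = 0.0697 without it). The count of 1.5-fold probe sets was 17, with 8 under a pseudocount at the 40th percentile and 32 without the filter (more probe sets). With fewer animals to agree, it was 34 without animal 5, 50 without animal 6 and 249 without animal 4. The number of animals is the same in each of these, so it does not alone account for the 249. Camera was not run with the animal as a random block.

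Lists past the threshold numbered 8 to 11 in camera's other settings and 0 with an estimated correlation and with fry. With an estimated correlation the adjusted p was 0.549 for developmental muscle and extracellular matrix, 0.56 for slow-twitch, denervation, adipocyte and fibroblast, 0.563 for fast-twitch, fatty acid and immune, and 0.632 for glycolysis. With fry it was 0.543 for glycolysis and fatty acids and 0.464 for the other 8. With 1 animal left out it ran from 1.05e-05 to 0.482 for glycolysis, 0.000665 to 0.218 for fatty acids and 1.27e-05 to 0.192 for immune markers. For the fibroblast list it was 0.0591 without the pairing and ipsilateral 4, and 0.221 without ipsilateral 6 as well. A call was gained for the neuromuscular junction list without the pairing and ipsilateral 4 (0.0193), and for the endothelial list without the filter (0.0446) and without the pairing and ipsilateral 4 and 6 (0.0168). The cause was not tested in these cases.

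Direction turned in 7 lists, none of them past camera's threshold, with these adjusted p-values where it turned and the range with 1 animal left out. For ubiquitin ligases it was 0.769 without the filter, 0.725 with the filter at the 60th percentile, 0.968 with fry and 0.813 without animal 4 (0.736 to 0.817). For oxidative phosphorylation it was 0.286 with quantile normalization, 0.297 without animal 4 (0.169 to 0.566), and 0.0915 and 0.856 in the settings chosen later. For growth factors it was 0.809 with the mean of probe sets, 0.536 without animal 4 (0.474 to 0.605), and 0.829 and 0.849 in the later settings. For ribosomal proteins it was 0.475 with quantile normalization, 0.985 without animal 6 (0.566 to 0.985) and 0.958 without ipsilateral 4 and 6. For the proteasome it was 0.547 without animal 4 and 0.986 without animal 5 (0.108 to 0.986), and 0.829 without ipsilateral 4. It was 0.817 for stress responses without animal 5 (0.437 to 0.817) and 0.769 for Schwann cells without the filter. The median and mean of the ubiquitin, growth factor and stress lists, or their test, differ in sign.

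Among 108 tested named genes 6 turned. Without ipsilateral 4 and 6 the log2 difference was -0.051 for Prm1, -0.046 for S100b and 0.41 for Slc4a1. For Prm1 the setting itself brings this about. It leaves out the ipsilateral libraries with the most Prm1. Without the pairing, it also sets ipsilateral 5 (intensity 72.4) against contralateral libraries that include contralateral 4 (175). Within the pair of animal 5 the difference was 0.28. With 1 animal left out the log2 difference ran from -0.47 to 0.053 for Hba-a3, -0.37 to 0.23 for Slc4a1, -0.021 to 0.49 for Chrnd and -0.048 to 0.078 for Myod1. The turned value was the one without animal 6 in each, and Myod1 was at -0.17 without ipsilateral 4. In at least 1 setting 42 of the 108 passed the adjusted threshold. Signal near background limits the dim genes, which were not tested.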

Other observations

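The test of imprinted genes was set beforehand, after 5 of them had been seen, and the reading of its result was changed afterwards.

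Several imprinted genes, of which 1 parental copy is expressed and many act in fetal growth, had a positive mean difference, ipsilateral minus contralateral, and were chosen after their values were seen. Nnat differed by 0.88 (SE 0.19), Mest by 0.37 (SE 0.17), Igf2 by 0.37 (SE 0.23), H19 by 0.33 (SE 0.16) and Dlk1 by 0.39 (SE 0.16), over 3 pairs each and none past limma's adjusted threshold. In animal 4 Igf2 was at -0.16 and H19 at -0.05. Mest, Igf2, H19 and Dlk1 also belong to the list of developing and regenerating muscle, so their differences are not separate from that list's rise. The hypothesis that imprinted genes shifted as a group was tested with camera on 11 others, and did not pass the p under 0.05 set beforehand (p = 0.104 upward, p = 0.23 with an estimated correlation). The prediction had counted such a p as evidence against the shift. That bound was badly set, since a p that misses a threshold excludes no shift, and the hypothesis is treated as undecided. Of the 11, 1 was higher and 1 lower in all 3 animals, and the median was 0.07. The largest were Cdkn1c, a cell cycle inhibitor, at 1.0 (SE 0.33) with -0.30 in animal 4, and the noncoding Meg3 at 0.88 (SE 0.24).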
